A study of Mus musculus with 4 samples.

How the data were processed

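Total RNA of 4 libraries was sequenced, 2 from mice on normal chow (NCD) and 2 from mice on a high-fat diet (HFD). Per the labels' protocols, isolated islets were frozen in liquid nitrogen, RNA was extracted with TRIzol and described as that of islet macrophages, and libraries were made with a stranded KAPA kit. Whether and how macrophages were separated from the other islet cells is not given in the sources used here. The values that the authors deposited are whole-number counts per gene, 1 table per library, over 55421 Ensembl gene identifiers. The submitters' processing notes name HISAT, featureCounts version 1.5.0, DESeq version 1.8.3 and build GRCm38, without the role or settings of each. The strand setting and the treatment of reads that match several genes are not given in the sources used here. Gene symbols, types and coordinates were taken from a GENCODE annotation of GRCm38, in which 55154 of the identifiers had a symbol. Samples were grouped by diet from their titles, which also give the replicate numbers.

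Totals were 64490097 and 62171973 counts in NCD and 61855337 and 56740720 counts in HFD. Low counts were more frequent at multiples of 4 than at their direct neighbours in each library, by a factor of 1.57 to 1.64. How many fragments stand behind a count is therefore unsure, and the precision of a single count may be lower than the totals give. A gene without a count in one diet was set against a floor of 12 counts per library, which is 3 steps of 4, and its change was given as a lower bound. This floor was chosen after the multiples of 4 were seen. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

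Counts were analysed in R 4.3.3. Genes passing edgeR's filterByExpr with a minimum count of 10 (21563 genes) were scaled by TMM and tested by edgeR 4.0.16 with the quasi-likelihood F test for diet, without a replicate block, at a Benjamini-Hochberg adjusted p under 0.05. CPM values use the TMM-scaled library sizes, except for sums over a list, which use the unscaled totals. The common biological coefficient of variation was 19.1%. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, for lists with at least 5 tested members, and again with an estimated correlation and with fry, which asks whether a list moves on balance one way. The 41 lists covered macrophage programmes, metabolism, stress, proliferation and the cell types an islet preparation can hold, and 38 had enough members. Members with too few counts for the filter were not tested, and list counts are out of the tested members unless stated otherwise. Lists sharing genes with others were the lipid-associated and cholesterol efflux lists (4 genes each), fatty acid synthesis (3), immediate early and matrix genes (2 each), and 13 lists with 1 shared gene each. Members called were counted with p adjusted over all genes and over the list alone.

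The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between the diets, leaving out names of clones and gene models. It also took up to 4 members of each list with the smallest p, and always Adgre1, Csf1r, Cd68, Itgax, Il1b, Tnf, Mrc1, Trem2, Ins1, Ins2, Gcg and Cpa1. Other genes named, such as those that moved against their list, 1700047I17Rik2, the Reg and complement genes and the rises without antigen receptor segments, were chosen after their values were seen. Variable segments, trypsinogens, H2-Q6 and H2-Q7, Hspa1b, Sumo2 and the ribosomal proteins have near-identical copies, and their counts are uncertain. The same holds for genes sharing exons with another gene. Some genes that the rule takes are not reported here.

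Alternatives were DESeq2's size factors, the Wald test of DESeq2 1.42.0, limma-voom, no count filter, a mean of at least 5 CPM, a replicate block, leaving out each library, library sizes without endocrine, acinar and most-counted genes (over 1% of a library), and a change of at least 2-fold. Alternatives chosen after seeing the data were counts divided by 4, tests without antigen receptor segments and lists reduced to genes of 1 list. When a diet kept 1 library, that library was assumed to vary like those of the other diet. Transcript length and GC content had Spearman correlations of 0.0302 and 0.0216 with the log2 change over 12727 genes. The test was run on simulated counts with known changes, where 0%, 24%, 88% and 100% of 50 genes each were recovered at 1.25-fold, 1.5-fold, 2-fold and 4-fold among 20860 genes, with 17 calls among unchanged genes. In camera's simulation a shift of the glycolysis list by 0.5 on the log2 scale was found (camera adjusted p = 3.06e-17). Simulated genes varied independently of each other, so this does not show how the list test fares when genes are correlated. Figures were drawn with matplotlib 3.10.9.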

Results

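RNA was sequenced from material that the labels name as islet macrophages of wild-type C57BL/6 mice, an inbred laboratory strain. A pair of libraries came from mice on normal chow (NCD) and a pair from mice on a high-fat diet (HFD), a feeding regime that makes mice obese and insulin resistant. The NCD libraries held 64490097 and 62171973 counts and the HFD libraries 61855337 and 56740720 counts over 55421 gene identifiers, of which 25517 to 27502 had a count in a given library. The most abundant transcripts were hormones of islet endocrine cells. In NCD, Ins2, which encodes insulin, stood at 9836 ± 84.6 CPM (counts scaled to library size; SD, n = 2) and Gcg, which encodes glucagon, at 9256 ± 311 CPM, while the macrophage gene Adgre1, which encodes F4/80, stood at 30.7 ± 1.70 CPM. Values of genes here are CPM after scaling between libraries, as mean ± SD over n = 2 libraries per diet. Sums over a list are given per library, without that scaling, and include members that were not tested. Pearson correlations across genes of log2 CPM were 0.976 and 0.977 within a diet and 0.937 in each pair of libraries between diets. Nothing in the labels says that the 2 libraries of a diet came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

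The comparison of HFD with NCD asked which transcripts differed with diet in libraries that the labels assign to islet macrophages and whose most abundant transcripts were endocrine. Transcripts of inflammatory mediators, of lymphocytes, of fibroblasts and of pancreatic acinar cells rose several-fold in HFD, while transcripts of beta cells and of protein folding in the endoplasmic reticulum fell. Il1b, encoding the cytokine IL-1β, rose from 6.61 ± 0.260 to 62.7 ± 0.265 CPM, and Col3a1, a fibrillar collagen, from 22.3 ± 0.126 to 532 ± 7.28. Ighm, the heavy chain of IgM antibodies, rose from 501 ± 1.34 to 3321 ± 26.1, and Cpa1, a digestive carboxypeptidase of acinar cells, from 35.6 ± 0.407 to 284 ± 30.02. Iapp, a peptide that beta cells secrete with insulin, fell from 5908 ± 235 to 3541 ± 104, and Hspa5, the main chaperone of the endoplasmic reticulum, from 2920 ± 72.1 to 2001 ± 9.31. Macrophage identity genes moved in both directions, and Adgre1 itself, at 25.4 ± 1.501 CPM in HFD, did not pass the test (edgeR adjusted p = 0.0726), though DESeq2 called it lower (DESeq2 adjusted p = 0.0180).

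Of 21563 genes tested with edgeR's quasi-likelihood test, 3860 were higher and 3123 lower in HFD at a Benjamini-Hochberg adjusted p under 0.05. The rises were larger than the falls, with a median log2 change of 1.18 among the genes that rose and a median fall of 0.48 among those that fell. A change of at least 2-fold was seen in 2160 genes that rose and 287 that fell. In all 6983 genes called, both libraries of one diet lay above both of the other, as they did in 67.7% of all genes tested, where chance gives 33.3%. Without HFD replicate 1 the number of genes lower in HFD was 2015. Camera, a test of whether the members of a list rank apart from other genes, called 20 of 38 lists higher and 4 lower, none of which passed when the correlation between genes was estimated (11 lists had an unadjusted p under 0.05 in that form, and the rotation test fry called 32 lists).

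**Figure D1:**
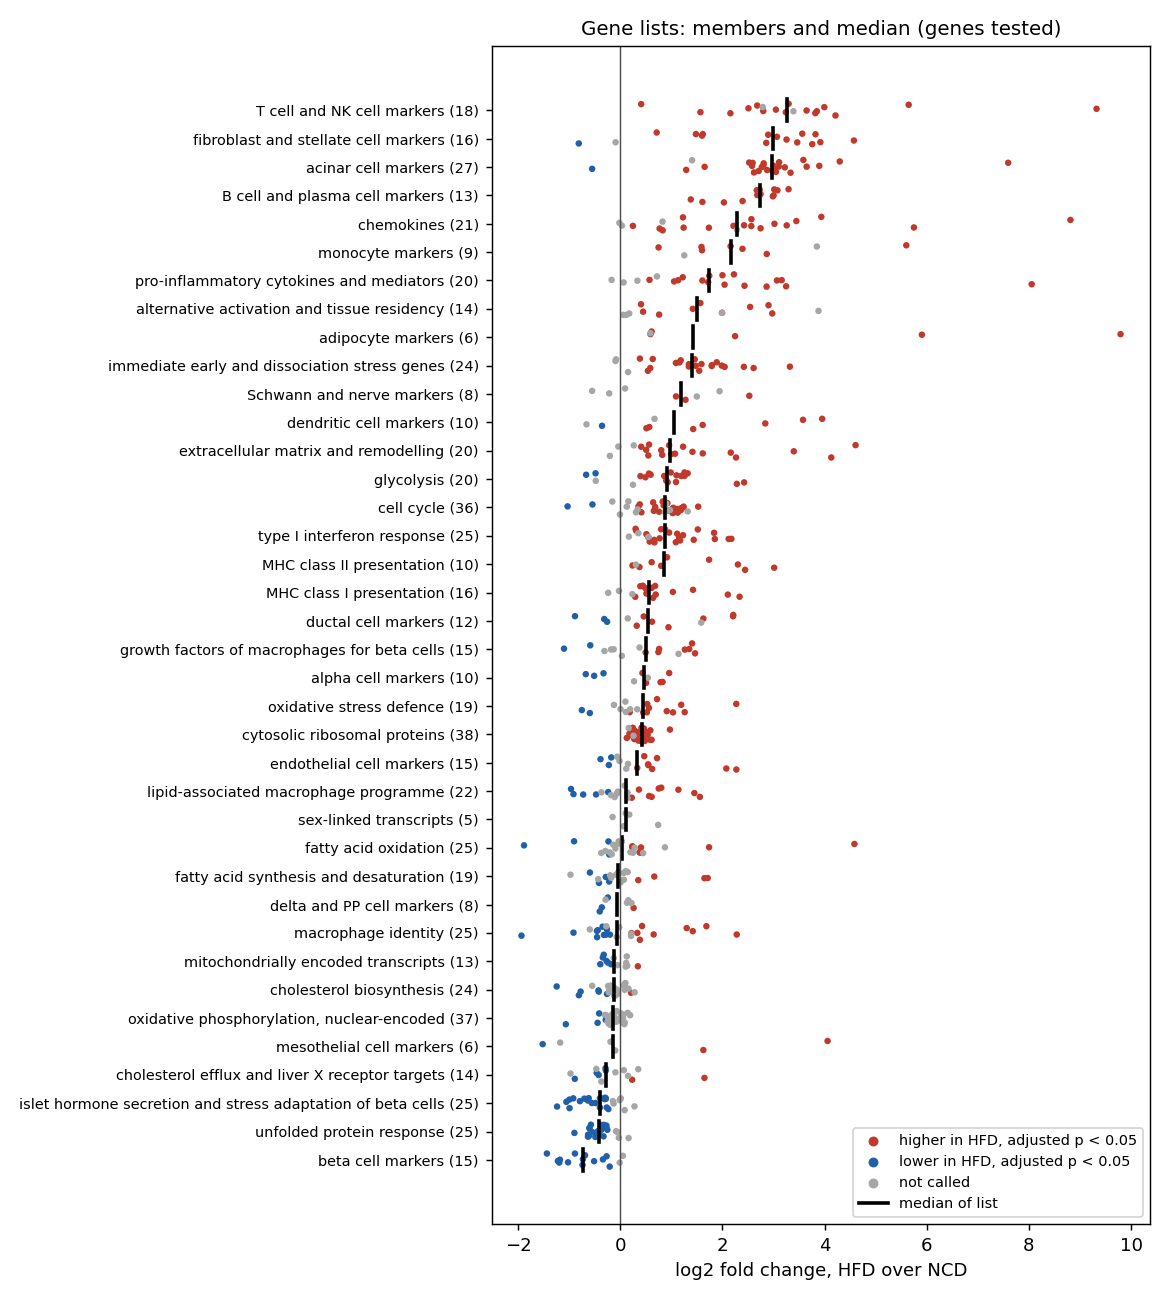
Each point is a tested gene of a list, placed by its log2 fold change of HFD over NCD (horizontal axis) and coloured by the edgeR call, and each black bar is the median of the list, with the number of genes tested in parentheses. Medians run from 3.27 for T cell and NK cell markers to -0.73 for beta cell markers.

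Among 25 macrophage identity genes, 9 rose and 10 fell (10 and 11 adjusted over the list alone), and the list did not stand apart from other genes (camera adjusted p = 0.765). Its median log2 change was -0.07 and its mean 0.10, so that the median and the camera direction differed in sign from the mean. Ptprc, encoding CD45 of all leukocytes, rose from 53.7 ± 1.49 to 132 ± 2.86 CPM and Cd14, a lipopolysaccharide co-receptor, from 32.3 ± 3.51 to 104 ± 9.30. Cd86, a co-stimulatory ligand, rose from 4.26 ± 0.247 to 20.7 ± 2.07 and the integrin gene Itgam from 20.2 ± 1.33 to 53.9 ± 6.54. Cx3cr1, the fractalkine receptor, fell from 10.99 ± 2.10 to 2.88 ± 0.182, and the integrin gene Itgax, which encodes CD11c, from 101 ± 0.276 to 53.4 ± 5.64. Cd68, a lysosomal glycoprotein, fell from 146 ± 2.08 to 122 ± 3.06 (edgeR adjusted p = 0.0129), a call lost without NCD replicate 1 or HFD replicate 1 (edgeR adjusted p = 0.0602 and 0.0711). Csf1r, the receptor of macrophage colony-stimulating factor, rose from 86.6 ± 5.09 to 101 ± 1.1 (edgeR adjusted p = 0.0489), a call lost without the count filter (0.0735), with a replicate block (0.0600) and without any 1 of the 4 libraries (0.0527 to 0.2). Summed over the list, the libraries held 2327 and 2237 CPM in NCD and 2190 and 2199 CPM in HFD.

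Inflammatory genes rose as groups. Of 20 pro-inflammatory cytokines and mediators 16 rose and 4 did not pass (16 rose adjusted over the list alone; camera adjusted p = 2.43e-08, and adjusted p = 0.157 with an estimated correlation), with a median log2 change of 1.73, or 1.66 with a gene at 0 in NCD set to its lower bound. Besides Il1b, Ptgs2, the inducible cyclooxygenase, rose from 21.1 ± 0.243 to 153 ± 2.95 CPM, the cytokine gene Tnf from 29.2 ± 3.05 to 97.8 ± 2.75, and Nfkbia, the inhibitor of NF-κB that NF-κB itself induces, from 124 ± 9.37 to 271 ± 13.3. Of 21 chemokine genes 17 rose (18 adjusted over the list alone), with a median log2 change of 2.28, or 2.27 with a gene at its bound (camera adjusted p = 6.85e-09, and adjusted p = 0.157 with an estimated correlation). They included the neutrophil attractants Cxcl2, from 11.8 ± 1.35 to 95.9 ± 3.07, and Cxcl3, from 1.89 ± 0.0630 to 29.0 ± 0.616, and the monocyte attractant Ccl2, from 12.5 ± 0.335 to 67.2 ± 3.18. Immediate early genes, which also respond to tissue dissociation, moved with them, as did markers of lymphocytes and fibroblasts. Of 24 such genes 21 rose (21 adjusted over the list alone; median log2 change 1.40, camera adjusted p = 7.84e-10, and adjusted p = 0.281 with an estimated correlation), among them Egr1, from 142 ± 0.770 to 525 ± 2.24, and the heat-shock gene Hspa1b, from 96.1 ± 1.64 to 396 ± 28.3, whose reads can be shared with its near-identical neighbour Hspa1a.

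Of 20 genes of alternative activation and tissue residency 14 had enough counts to be tested, of which 9 rose and 5 did not pass (10 rose adjusted over the list alone). The 6 untested were Cbr2, Cd163, Chil3, Chil4, Retnla and Timd4, and those that did not pass were Clec10a, Mgl2, Lyve1, Stab1 and Mrc1. The alternative activation list had a median log2 change of 1.49 (camera adjusted p = 2.66e-05, and adjusted p = 0.157 with an estimated correlation). Il4ra, the receptor chain for IL-4 and IL-13, rose from 65.9 ± 0.0390 to 176 ± 4.54 CPM, and Maf, a transcription factor of resident macrophages that lymphocytes also express, from 8.26 ± 0.314 to 32.8 ± 2.00. Mrc1, the mannose receptor used as a marker of alternative activation, stood at 17.8 ± 1.52 in NCD and 18.5 ± 3.17 in HFD (edgeR adjusted p = 0.813). Of 25 type I interferon response genes 22 rose (22 adjusted over the list alone). Interferon response genes had a median log2 change of 0.87 (camera adjusted p = 7.02e-09, and adjusted p = 0.157 with an estimated correlation). Isg15, a ubiquitin-like antiviral protein, rose from 3.16 ± 0.394 to 14.3 ± 1.01, and Irf7, a transcription factor of the response, from 8.42 ± 0.385 to 24.1 ± 1.56. Of 10 genes of MHC class II presentation 9 rose (10 adjusted over the list alone). MHC class II genes had a median log2 change of 0.86 (camera adjusted p = 6.83e-05, and adjusted p = 0.157 with an estimated correlation). The class II master regulator Ciita rose from 3.92 ± 0.680 to 19.4 ± 1.84, and Cd74, the invariant chain, from 580 ± 18.1 to 888 ± 79.9. H2-Ob, which is mainly a B cell gene, rose from 1.85 ± 0.176 to 14.9 ± 0.980, in libraries whose B cell markers also rose. Of 16 genes of MHC class I presentation 13 rose, and adjusted over the list alone 13 rose and 1 fell. MHC class I genes had a median log2 change of 0.56 (camera adjusted p = 2.97e-05, and adjusted p = 0.157 with an estimated correlation). B2m, the light chain of class I molecules, rose from 498 ± 12.03 to 1017 ± 22.4, while the rise of the paralogs H2-Q6 and H2-Q7 is uncertain because such genes share reads.

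Lipid-associated macrophage genes split. Of 22 such genes 9 rose and 5 fell (11 and 6 adjusted over the list alone), with a median log2 change of 0.11 (camera adjusted p = 0.529). Plin2, which coats lipid droplets, rose from 140 ± 9.11 to 382 ± 3.03 CPM and Spp1, encoding osteopontin, from 608 ± 25.6 to 1791 ± 149. Lpl, the lipoprotein lipase, fell from 443 ± 3.23 to 268 ± 7.15, and Trem2, the lipid-sensing receptor of this programme, from 31.7 ± 3.84 to 16.3 ± 1.20 (edgeR adjusted p = 0.00315). Of 15 growth factor genes 7 rose and 2 fell, the same numbers as adjusted over the list alone. The growth factor list had a median log2 change of 0.50 (camera adjusted p = 0.232). Ccn2, encoding a matrix-associated growth factor, rose from 9.82 ± 0.103 to 23.6 ± 2.73, and Egf fell from 17.7 ± 1.77 to 8.25 ± 0.649, together with Vegfb, from 36.7 ± 0.681 to 24.4 ± 0.928.

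**Figure D2:**
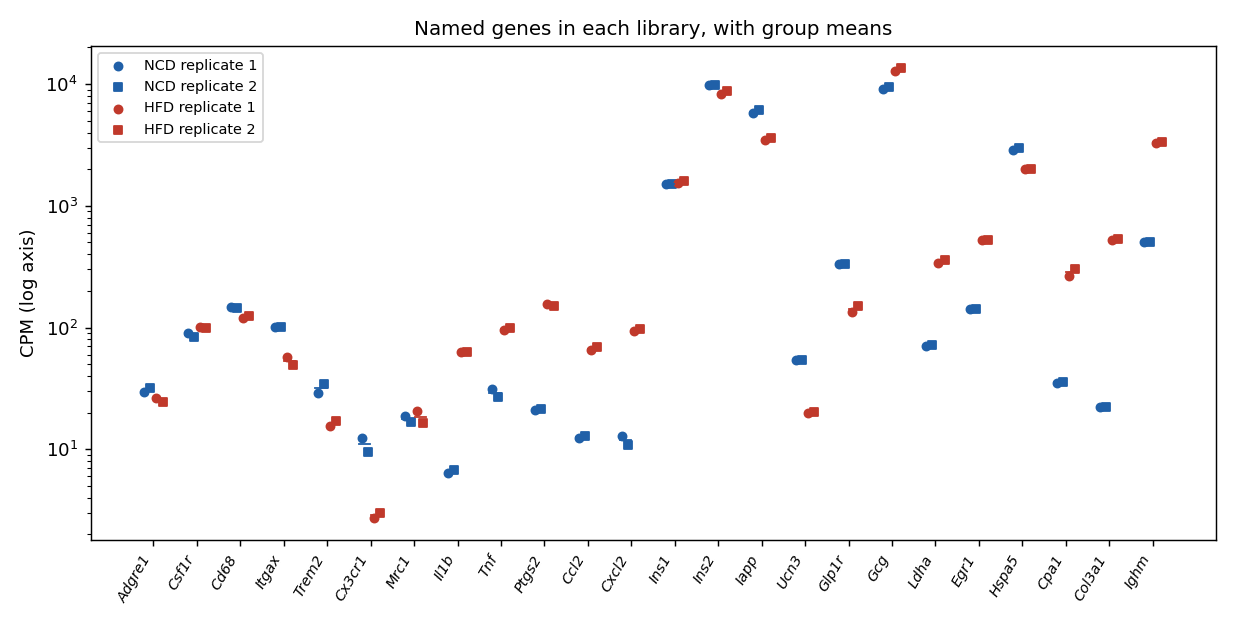
Points give the CPM of 24 genes in each of the 4 libraries (log axis), with a horizontal line at the mean of each diet. Il1b stood at 6.42 and 6.79 CPM in NCD and at 62.9 and 62.5 CPM in HFD, while Mrc1 had means of 17.8 CPM in NCD and 18.5 CPM in HFD.

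Markers of lymphocytes and of other leukocytes rose. All 13 B cell and plasma cell markers rose (13 adjusted over the list alone). B cell and plasma cell markers had a median log2 change of 2.73 (camera adjusted p = 1.12e-09, and adjusted p = 0.157 with an estimated correlation), and their sum went from 732 and 740 CPM in NCD to 4772 and 4795 CPM in HFD. Jchain, which joins antibody polymers, rose from 29.2 ± 0.688 to 236 ± 6.43. Antibody and T cell receptor genes together took 0.104% ± 0.000163 of the counts in NCD and 0.674% ± 0.000875 in HFD, and 167 of their 198 tested segments were higher and 7 lower. Of 18 T cell and NK cell markers 16 rose (18 adjusted over the list alone). T cell and NK cell markers had a median log2 change of 3.27, or 3.14 with a gene at its bound (camera adjusted p = 4.41e-08, and adjusted p = 0.157 with an estimated correlation). Their levels stayed low, as for Cd3e, a chain of the T cell receptor complex, which rose from 0.616 ± 0.0160 to 6.07 ± 1.04. Of 9 monocyte markers 7 rose (9 adjusted over the list alone). Monocyte markers had a median log2 change of 2.16 (camera adjusted p = 2.66e-05, and adjusted p = 0.157 with an estimated correlation). Vcan, a matrix proteoglycan that fibroblasts also make, rose from 9.18 ± 0.505 to 67.0 ± 3.10. Of 10 dendritic cell markers 7 rose and 1, Dpp4, fell, as adjusted over the list alone. Dendritic cell markers had a median log2 change of 1.05 (camera adjusted p = 0.00291, and adjusted p = 0.206 with an estimated correlation). Ccr7, the homing receptor of lymphocytes and mature dendritic cells, rose from 7.72 ± 0.593 to 92.2 ± 15.0. Neutrophil, mast cell and erythroid lists, of 13, 9 and 9 genes, had too few tested genes for the list test. In these 1 of 3, 2 of 2 and 3 of 4 tested genes passed as higher (1, 2 and 4 adjusted over the list alone), with Lcn2 at 147 ± 4.21 in NCD and 149 ± 6.31 in HFD, Kit rising from 56.4 ± 4.48 to 117 ± 1.85, and the haemoglobin gene Hba-a1 at 1.27 ± 0.157 and 3.79 ± 1.68. All of these calls but that of Kit were lost when some library was left out. Without NCD replicate 1, NCD replicate 2 and HFD replicate 2, edgeR adjusted p was 0.0677, 0.0925 and 0.122 for Hba-a1, 0.0807, 0.148 and 0.197 for Hbb-bs, and 0.103, 0.101 and 0.131 for Tpsb2. Without HFD replicate 1 it was 0.110 for Hbb-bt and 0.0545 for Mmp8. With a replicate block it was 0.0569 for Hba-a1, 0.114 for Hbb-bs and 0.103 for Tpsb2, and without the count filter 0.0698 for Hbb-bs and 0.0663 for Tpsb2. Limma-voom gave an adjusted p of 0.134 for Hbb-bs.

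Exocrine and stromal markers rose. Of 27 acinar cell markers 25 rose, 1, the transcription factor gene Bhlha15, fell, and 1 did not pass (26 rose and 1 fell adjusted over the list alone). Acinar markers had a median log2 change of 2.98, or 2.88 with a gene at its bound (camera adjusted p = 1.99e-13, and adjusted p = 0.216 with an estimated correlation). Their sum went from 609 and 643 CPM in NCD to 4070 and 4540 CPM in HFD. Pnlip, the pancreatic lipase, rose from 48.3 ± 1.87 to 391 ± 29.1, and the trypsinogen genes Prss2 and Try5, paralogs whose reads can be shared, from 47.7 ± 1.38 to 334 ± 5.33 and from 25.7 ± 0.933 to 213 ± 1.74. Of 16 fibroblast and stellate cell markers 14 rose and 1, Mgp, fell, as adjusted over the list alone. Fibroblast and stellate cell markers had a median log2 change of 2.98 (camera adjusted p = 6e-08, and adjusted p = 0.157 with an estimated correlation). Col1a1 rose from 13.01 ± 0.593 to 176 ± 5.30 and Dcn, encoding the proteoglycan decorin, from 20.2 ± 1.05 to 193 ± 10.5. Of 20 extracellular matrix and remodelling genes 17 rose, and adjusted over the list alone 18 rose and 1 fell. Matrix genes had a median log2 change of 0.98 (camera adjusted p = 7.05e-08, and adjusted p = 0.157 with an estimated correlation). Fn1, encoding fibronectin, rose from 31.2 ± 2.38 to 328 ± 24.9, and Mmp9, a gelatinase, from 1.24 ± 0.155 to 30.3 ± 2.71.

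Of 15 endothelial markers 8 rose and 3 fell (9 and 3 adjusted over the list alone). Endothelial markers had a median log2 change of 0.33 (camera adjusted p = 0.0455, and adjusted p = 0.281 with an estimated correlation), a call also lost with a replicate block and without NCD replicate 1, NCD replicate 2 or HFD replicate 2 (camera adjusted p = 0.0717, 0.118, 0.0755 and 0.0970). Vwf, encoding von Willebrand factor, rose from 14.8 ± 1.66 to 71.4 ± 0.190 CPM, whereas Esm1, Kdr and Flt1 fell. Of 12 ductal markers 7 rose and 3 fell (8 and 3 adjusted over the list alone; median log2 change 0.54, camera adjusted p = 0.0786), with the keratin genes Krt8 higher, from 238 ± 5.36 to 458 ± 29.5, and Krt7 lower, from 445 ± 4.04 to 241 ± 13.3. Of 10 adipocyte markers 6 were tested and 5 rose (5 adjusted over the list alone). Adipocyte markers had a median log2 change of 1.43 (camera adjusted p = 0.00241, and adjusted p = 0.206 with an estimated correlation). The fatty acid carrier gene Fabp4, which macrophages also express, rose from 77.2 ± 2.83 to 118 ± 2.94. Cfd, encoding the adipocyte product adipsin, had no count in NCD and stood at 1.81 ± 0.733 in HFD, at least 9.53-fold higher than a floor of 12 counts per library. Of 8 Schwann cell and nerve markers 3 rose (4 rose and 1 fell adjusted over the list alone; median log2 change 1.18, camera adjusted p = 0.126), among them Ngfr, a neurotrophin receptor, from 3.31 ± 0.361 to 8.03 ± 0.113. Of 6 mesothelial markers 2 rose and 1 fell, the same numbers as adjusted over the list alone (median log2 change -0.15, mean 0.45, camera adjusted p = 0.890), with Wt1, a transcription factor gene, higher, from 0.386 ± 0.0680 to 6.47 ± 0.558, and Msln, encoding mesothelin, lower, from 37.6 ± 0.256 to 13.1 ± 1.247.

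**Figure D3:**
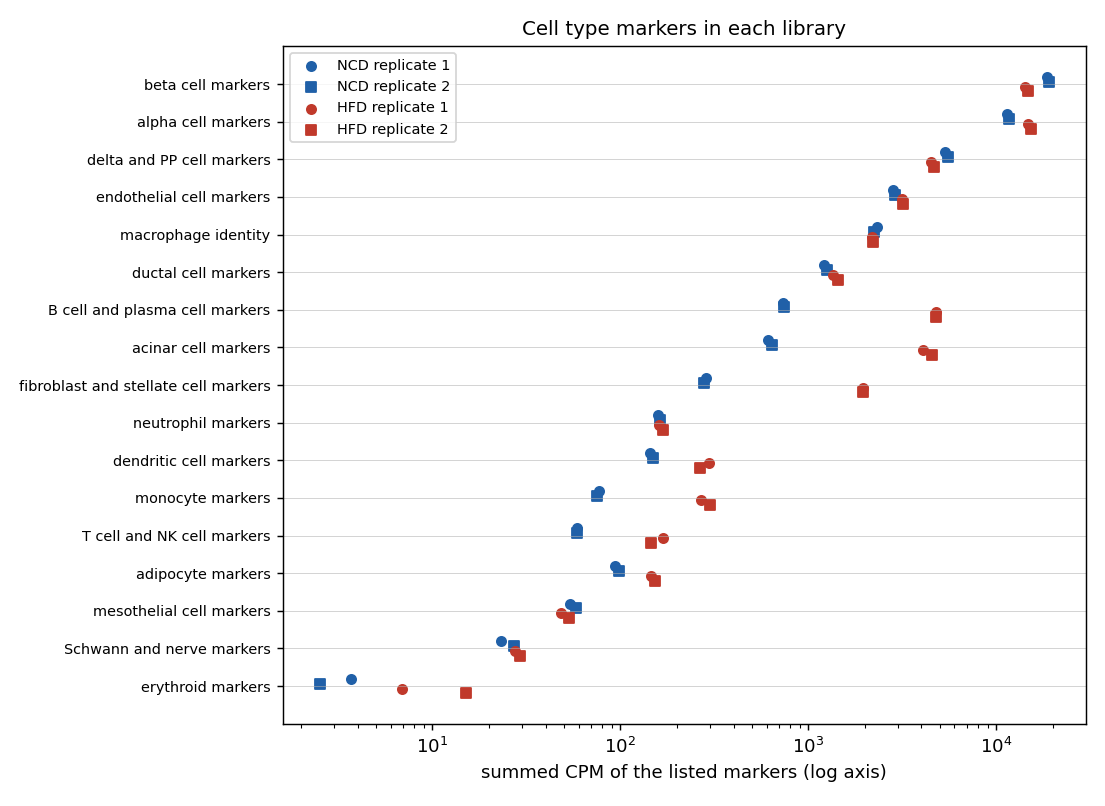
Points give the summed CPM of the markers of each cell type in each of the 4 libraries (log axis). Acinar markers sum to 609 and 643 CPM in NCD and to 4070 and 4540 CPM in HFD, while macrophage identity genes sum to 2190 to 2327 CPM in all 4 libraries.

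Beta cell transcripts fell while glucagon rose. Of 15 beta cell markers 13 fell (13 adjusted over the list alone). Beta cell markers had a median log2 change of -0.73 (camera adjusted p = 3.71e-06, and adjusted p = 0.157 with an estimated correlation), and their sum went from 18548 and 19111 CPM in NCD to 14302 and 14758 CPM in HFD. Ucn3, a peptide hormone of mature beta cells, fell from 54.1 ± 0.454 to 20.007 ± 0.261 CPM, and Slc30a8, the zinc transporter of insulin granules, from 135 ± 3.16 to 59.3 ± 1.40. Ins2 fell to 8522 ± 299 (edgeR adjusted p = 0.00466), whereas Ins1 stood at 1512 ± 12.6 in NCD and 1566 ± 49.9 in HFD (edgeR adjusted p = 0.320). Of 25 genes of islet hormone secretion and beta cell stress adaptation 19 fell (20 adjusted over the list alone). Secretion genes had a median log2 change of -0.40 (camera adjusted p = 2.29e-06, and adjusted p = 0.215 with an estimated correlation). Abcc8, a subunit of the potassium channel that triggers insulin release, fell from 1286 ± 17.9 to 744 ± 4.85, and Glp1r, the receptor of the incretin GLP-1, from 335 ± 1.18 to 142 ± 12.4. Of 10 alpha cell markers 5 rose and 3 fell (6 and 3 adjusted over the list alone). Alpha cell markers had a median log2 change of 0.47 (camera adjusted p = 0.337). Gcg rose to 13138 ± 465 (edgeR adjusted p = 0.000452) and Ttr, encoding transthyretin, from 161 ± 9.37 to 312 ± 10.2, while Peg3 fell from 1564 ± 47.7 to 979 ± 42.8. Of 8 delta and PP cell markers 1 rose and 3 fell, the same numbers as adjusted over the list alone. Delta and PP cell markers had a median log2 change of -0.06 (camera adjusted p = 0.596). The 3 that fell were the hormone genes Sst, from 3912 ± 133 to 3304 ± 114, Ppy, from 417 ± 9.57 to 316 ± 5.56, and Pyy, from 826 ± 3.15 to 643 ± 40.1.

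Genes of the unfolded protein response, which serve protein folding in secretory cells, fell together with the beta cell markers. Of 25 such genes 21 fell and 4 did not pass, and adjusted over the list alone 21 fell and 1 rose. The unfolded protein response list had a median log2 change of -0.42 (camera adjusted p = 1.66e-07, and adjusted p = 0.256 with an estimated correlation). Besides Hspa5, Hyou1 fell from 641 ± 3.92 to 414 ± 7.55 CPM, Sdf2l1 from 133 ± 1.33 to 71.6 ± 2.07, and Calr, encoding calreticulin, from 1689 ± 74.0 to 1105 ± 1.70. Oxidative stress defence genes mostly rose, with 11 of 19 higher and 2, the metallothionein genes Mt1 and Mt2, lower (12 and 2 adjusted over the list alone). The oxidative stress list had a median log2 change of 0.45 (camera adjusted p = 0.00362, and adjusted p = 0.462 with an estimated correlation). Slc7a11, the cystine importer, rose from 83.5 ± 2.06 to 403 ± 17.5, and the peroxiredoxin gene Prdx1 from 467 ± 9.58 to 1067 ± 4.46.

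Glycolysis genes rose, with 16 of 20 higher and 2, Pfkm and Eno2, lower, as adjusted over the list alone. The glycolysis list had a median log2 change of 0.91 (camera adjusted p = 8.26e-06, and adjusted p = 0.215 with an estimated correlation). Ldha, lactate dehydrogenase A, which beta cells keep low, rose from 71.7 ± 0.815 to 349 ± 14.8 CPM, Pgk1 from 250 ± 3.30 to 571 ± 3.80, Eno1 from 377 ± 9.73 to 803 ± 13.1 and Pkm from 879 ± 0.158 to 1640 ± 22.3. Acinar, stromal and immediate early genes rose in the same libraries. Of 37 nuclear genes of oxidative phosphorylation 8 fell and 29 did not pass (6 fell adjusted over the list alone; median log2 change -0.14, camera adjusted p = 0.00597, and adjusted p = 0.462 with an estimated correlation), a call also lost among genes with a mean of at least 5 CPM (camera adjusted p = 0.0861). Cox8a, a subunit of cytochrome c oxidase, fell from 111 ± 3.02 to 53.0 ± 0.378. Of 13 mitochondrially encoded transcripts 1, mt-Nd1, rose and 6 fell (3 and 7 adjusted over the list alone; median log2 change -0.13, camera adjusted p = 0.262), mt-Co3 from 1642 ± 27.5 to 1252 ± 17.4. Of 24 cholesterol biosynthesis genes 1, Idi1, rose and 6 fell, the same numbers as adjusted over the list alone (median log2 change -0.13, camera adjusted p = 0.0542), a list that passed without NCD replicate 1 (camera adjusted p = 0.0178). Insig1, which restrains sterol synthesis, fell from 261 ± 3.82 to 194 ± 4.10 CPM. Fdps, a farnesyl diphosphate synthase that shares exon sequence with another gene, fell from 171 ± 6.71 to 99.99 ± 11.5.

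Camera did not call the other lipid lists. Of 14 genes of cholesterol efflux and liver X receptor targets 2 rose and 5 fell, the same numbers as adjusted over the list alone (median log2 change -0.29, camera adjusted p = 0.325), with Abcg1, a cholesterol exporter, lower, from 135 ± 0.892 to 73.0 ± 2.94 CPM. Of 19 genes of fatty acid synthesis and desaturation 4 rose and 4 fell (4 and 5 adjusted over the list alone; median log2 change -0.04, mean 0.07, camera adjusted p = 0.656). Acly, which makes cytosolic acetyl-CoA, fell from 1831 ± 4.34 to 1213 ± 2.95, and Scd1, a stearoyl-CoA desaturase, rose from 18.5 ± 0.310 to 57.9 ± 2.39. Of 25 fatty acid oxidation genes 7 rose and 4 fell, the same numbers as adjusted over the list alone. Fatty acid oxidation genes had a median log2 change of 0.03 (camera adjusted p = 0.777), and fry called the list higher (fry adjusted p = 0.0379). Hadh fell from 232 ± 8.41 to 124 ± 0.845, and Pdk4, which inhibits pyruvate dehydrogenase, rose from 7.60 ± 0.105 to 25.4 ± 0.617.

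Cell cycle genes rose, with 24 of 36 higher and 2, Ccnd2 and Foxm1, lower (26 and 2 adjusted over the list alone). The cell cycle list had a median log2 change of 0.88 (camera adjusted p = 5.09e-06, and adjusted p = 0.157 with an estimated correlation). Mki67, the proliferation antigen Ki-67, rose from 24.1 ± 1.99 to 54.8 ± 2.60 CPM, and Mcm5, part of the replicative helicase, from 8.76 ± 0.327 to 20.6 ± 0.0350, in libraries whose lymphocyte markers also rose. Ccnd2, the main D-type cyclin of beta cells, fell from 536 ± 5.54 to 367 ± 1.49. Of 38 cytosolic ribosomal protein genes 36 rose (37 adjusted over the list alone). Ribosomal protein genes had a median log2 change of 0.42 (camera adjusted p = 7.02e-09, and adjusted p = 0.277 with an estimated correlation). Rplp0 rose from 696 ± 4.79 to 1065 ± 5.67, although such genes share reads with many pseudogenes. Ribosomal RNA, nuclear and mitochondrial together, took 0.730% ± 0.419 of the counts in NCD and 0.661% ± 0.104 in HFD. Mitochondrial transcripts, which include the mitochondrial ribosomal RNA again, took 2.54% ± 0.105 and 2.28% ± 0.0223. Of 5 sex-linked transcripts none was called by edgeR, over all genes or over the list alone, and none had an unadjusted p under 0.05, while DESeq2 called Eif2s3y lower (DESeq2 adjusted p = 0.0442; median log2 change of the list 0.10, camera adjusted p = 0.656). This Y-linked gene stood at 89.7 ± 3.74 in NCD and 80.8 ± 2.07 in HFD.

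The 10 largest rises among genes with a mean of at least 5 CPM were all variable segments of antibody genes without a count in either NCD library. Ighv1-18 (chromosome 12, 114682632 to 114683065, GRCm38) stood at 30.02 ± 0.512 CPM in HFD, at least 158-fold above a floor of 12 counts per library, and Ighv1-84, the last of the 10, at 11.8 ± 0.651, at least 62.3-fold above it. The others included Ighv4-1, Ighv5-15, Ighv8-8, Igkv10-94, Igkv4-68, Igkv12-44 and Igkv4-79. Variable segments of one family share reads. Of 209 variable segments with a count, 64 had at least 12 counts in both HFD libraries and none in either NCD library, and 1 had the reverse. Another 11 had at least 12 counts in 1 HFD library and none in the other, and 2 did so between the NCD libraries. The HFD libraries held 137818 and 125854 segment counts and the NCD libraries 22093 and 21060. Thinned to the lowest of these totals, 111 and 112 segments had at least 12 counts in HFD, against 54 and 52 in NCD. Leaving out antibody and T cell receptor segments, a step chosen after the values were seen, the largest rise was that of Cxcl13, the chemokine that attracts B cells, from 0.320 ± 0.271 to 17.4 ± 1.83 CPM. Other large rises were those of Fndc1, from 0.472 ± 0.122 to 21.9 ± 0.359, and of Col12a1, a collagen gene, from 2.18 ± 0.0120 to 86.4 ± 2.86. They also included Abca8a, Mmp9, the oxygen-sensing hydroxylase gene Egln3, from 2.52 ± 0.892 to 60.3 ± 0.133, and Col3a1.

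The largest fall was that of Fam177a (chromosome 12, 55124469 to 55142104), from 48.8 ± 2.33 CPM to no count in either HFD library, at least 241-fold below NCD against a floor of 12 counts per library. Its near-identical neighbour 1700047I17Rik2, named after its values were seen, held 58.5 ± 2.76 CPM in NCD and 59.2 ± 1.83 in HFD, and all 3833 of its 31-base words also occur in the Fam177a transcript, so the fall of Fam177a alone is uncertain. Sumo2, a ubiquitin-like modifier with processed copies elsewhere in the genome, fell from 107 ± 29.7 to 13.4 ± 0.585. Of the others, Igkv3-5, Igkv3-10 and Ighv1-52 are antibody segments, and Cx3cr1 is given with the macrophage genes. Mapt, encoding the microtubule protein tau, fell from 42.8 ± 1.83 to 11.98 ± 0.473, Gprasp2, a sorting protein of receptors, from 31.3 ± 2.84 to 8.20 ± 0.210, Fam151a from 107 ± 4.58 to 31.7 ± 2.28, and Otoa from 9.72 ± 0.05 to 2.79 ± 0.427.

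Among the genes named whatever their result, Il1b (ENSMUSG00000027398) lies on chromosome 2 from 129364570 to 129371139, Itgax (ENSMUSG00000030789) on chromosome 7 from 128129547 to 128150657, and Trem2 (ENSMUSG00000023992) on chromosome 17 from 48346401 to 48354147. Csf1r (ENSMUSG00000024621) lies on chromosome 18 from 61100598 to 61132149, Ins2 (ENSMUSG00000000215) on chromosome 7 from 142678656 to 142743381, Gcg (ENSMUSG00000000394) on chromosome 2 from 62474530 to 62483650, and Cpa1 (ENSMUSG00000054446) on chromosome 6 from 30639218 to 30645363. All coordinates are those of whole genes in build GRCm38. Genes named because they moved against the rest of their list were chosen after their values were seen. Col3a1, Itgam, Spp1, Cd74, Pkm, mt-Co3, mt-Nd1 and Gprasp2 share exon sequence with another annotated gene, so their counts are uncertain to that extent.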

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

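The tests with counts divided by 4, without antigen receptor segments and with genes of 1 list only were chosen after seeing the data. Across all settings, no gene called in the full analysis was called in the opposite direction, and of the named genes' values 2481 kept their direction and side of the threshold, 8 crossed into it, 48 left it and 4 changed sign. Those 4 were of the gene Mrc1 and the gene Lcn2, which were not called in any setting, with log2 changes from -0.12 to 0.22 and from -0.0331 to 0.0652 when 1 library was left out. The number of genes higher ranged from 2710 to 3224 and the number lower from 2015 to 2174 when 1 library was left out, with 2015 without HFD replicate 1, a setting with 1 library fewer. A threshold of at least 2-fold left 2160 genes higher and 287 lower, by its own construction. DESeq2 called 4959 higher and 4302 lower, limma-voom 3958 and 3277, DESeq2's size factors 3902 and 3025, no count filter 3391 and 2635, and a mean of at least 5 CPM 3137 and 2641. Library sizes without endocrine, acinar and most-counted genes gave 3870 and 3067, tests without antigen receptor segments 3687 and 3068, and counts divided by 4 gave 3985 and 3239. The labels share only numbers between diets, and same-numbered libraries did not deviate together (correlation across genes 0.00211), while the replicate block gave 3252 genes higher and 2583 lower. Of the lists, 0 were higher and 0 lower with an estimated correlation, against 20 and 4 with the preset one. In that form camera also takes its degrees of freedom from the 4 libraries rather than from all genes. The loss of calls can therefore not be assigned to correlation between genes alone. With fry, the mesothelial list turned from lower, not called by camera, to higher (fry adjusted p = 0.0379). Directions of lists without a call also turned, for macrophage identity with fry and at a mean of at least 5 CPM (adjusted p = 0.116 and 0.930), for fatty acid synthesis with fry (0.405) and for the mesothelial list with the replicate block (0.995). With 1 library left out they turned in some settings for the list fatty acid oxidation (camera adjusted p from 0.635 to 0.948) and the list mesothelial cell markers (0.689 to 0.972). Fry also called 7 lists that camera did not, with the alpha cell (0.00620), ductal (0.0158), lipid-associated (0.0201), Schwann (0.0202), growth factor (0.0219) and fatty acid oxidation (0.0379) lists higher and cholesterol biosynthesis (0.0417) lower. Camera called the Schwann list without NCD replicate 2 (camera adjusted p = 0.0347), and the cause of these changes was not tested. Among genes with a mean of at least 5 CPM, correlations between libraries were 0.982 within NCD and 0.880 between NCD replicate 2 and HFD replicate 1. The pseudocount and low-value filter alternatives, meant for deposited values that are not counts, did not apply and were not run. In simulated counts the test found 24% of 1.5-fold changes, while in the libraries the median fall among called genes was 0.48 on the log2 scale, so the simulation sets no lower limit on the changes called.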

Other observations

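The lymphoid tissue and low-oxygen lists were chosen after seeing the data, and the tests of endocrine share, macrophage share, replicate origin and multiples of 4 were chosen only after the result was seen. The tests of the lymphoid tissue and low-oxygen lists were set before those lists' values were looked at.

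Reg1, Reg2 and Reg3b encode secreted proteins of acinar and islet cells. Reg1, itself among the acinar markers, rose from 8.41 ± 0.241 to 50.3 ± 0.956 CPM (SD, n = 2; edgeR adjusted p = 6.05e-05), Reg2 9.35-fold and Reg3b 11.3-fold (edgeR adjusted p = 0.00212 and 0.000190), in libraries whose acinar markers rose with a median log2 change of 2.98. C3, the central complement protein, rose 10.3-fold from 70.9 ± 3.77 to 732 ± 6.88, C4b rose 13.4-fold from 9.71 ± 1.17 to 130 ± 0.365, C1s1 rose 9.36-fold and Cfb rose 2.74-fold, in libraries whose fibroblast and stellate cell markers also rose (median log2 change 2.98). The C1q genes, which tissue macrophages make, were lower, C1qa from 86.5 ± 4.05 to 71.3 ± 1.02, C1qb from 88.9 ± 4.59 to 71.2 ± 2.51 and C1qc from 71.9 ± 1.56 to 52.5 ± 1.46 (edgeR adjusted p = 0.0213, 0.0171 and 0.00411). These genes were chosen after their values were seen, and neither family was tested as a list.

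Acinar, stromal, lymphoid and inflammatory genes were higher together in HFD. A lower endocrine share that raises all other cell types alike is argued against by list medians of acinar, stromal, endothelial, macrophage and B cell genes that spanned 3.05 on the log2 scale, and a larger share of macrophages by their median log2 change of -0.0706. The prediction for lymphoid tissue carried over with the islets was met, since 6 of 7 tested genes were called higher. The genes are those of lymphoid stroma, high endothelial venules and follicles, with Chst4 of the 8 listed untested. Camera gave p = 3.23e-05, and p = 0.0599 with an estimated correlation. Ccl19, Ccl21a and Glycam1 had no count in NCD, and Madcam1 and Tnfsf11 had 7 and 5 counts in NCD replicate 1 only. These genes passed the filter only through HFD and could hardly come out lower, so the number called cannot decide. Cr2, counted in both diets, was called higher (edgeR adjusted p = 0.00619), and Fcer2a was not (edgeR adjusted p = 0.0883). Whether carried-over lymphoid tissue accounts for the lymphocyte part stays open. Glycam1 had no count in NCD and 1.23 ± 0.220 CPM in HFD, at least 6.50-fold higher, and Madcam1 went from 0.0540 ± 0.0770 to 2.10 ± 0.524. Ccl21a, also without a count in NCD, was uneven between the HFD libraries, with 653 and 203 counts. Lymphoid structures formed within islets on the diet, and a change of islet tissue with diet in general, stay open and were not tested. The span of medians argues only against a rise that is alike in all of these lists. No test addressed how much acinar and stromal tissue each preparation held, so differences in preparation cannot be told apart from diet.

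Libraries of one diet were nearly alike, and the variable antibody segments in them resembled each other more within a diet than between diets. Their counts, thinned to one depth, correlated at 0.930 in NCD and 0.955 in HFD across 209 segments, against 0.437 to 0.454 between diets. Inbred mice share the same germline segments, but clones that expand differ between animals, so replicates drawn from the same animals or RNA pool may explain this. A diet effect on segment use, in separate animals or in pools of several animals per library, would give the same pattern and stays open. Within a diet, 11 segments in HFD and 2 in NCD had at least 12 counts in 1 library and none in the other. A single library deposited under 2 names is argued against by ribosomal RNA shares, while chi-square ratios within a diet at low counts cannot decide. In genes with 20 to 200 counts the ratios were 5.72 in HFD and 5.86 in NCD, above the step of 4 counts. Copy numbers that vary around 4 could also lift the ratio of a resampled library above 4. They were 10.9 in HFD and 11.5 in NCD in far more counted genes. Ribosomal RNA, nuclear and mitochondrial together, took 1.03% and 0.434% of the counts in the NCD libraries and 0.735% and 0.587% in the HFD libraries. Resampling of 1 library was not simulated.

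Low counts were more frequent at multiples of 4, by a factor of at least 1.57 over their direct neighbours, while from 1004 to 2092 counts the factor was 0.919 to 1.03. In NCD replicate 1, 1026 genes had a count of 4, against 558 at 3 and 596 at 5. An exact scaling in which 1 fragment is worth 4 counts is argued against, since at least 69.1% of the genes with 1 to 99 counts lay off multiples of 4 in each library. The same share leaves open PCR duplicates with copy numbers that vary around 4. The chi-square ratio between replicates in genes with 20 to 200 counts was 5.72 in HFD and 5.86 in NCD. These ratios lay above the range predicted for such duplicates. Other differences between replicates also enter the ratio, so it cannot decide. How the counts were made is not given in the sources used here, and no biological explanation was tested.

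The glycolysis list was higher in HFD together with 15 of 18 low-oxygen response genes outside it, whose median log2 change was 0.65 (camera p = 2.34e-06, and p = 0.0377 with an estimated correlation). Car9 rose from 0.863 ± 0.212 to 8.66 ± 0.392 CPM and Adm from 2.44 ± 0.317 to 15.4 ± 2.64. Mxi1, Narf and Vldlr were not called. Acinar, fibroblast and lymphocyte markers rose in the same libraries, so a low-oxygen response cannot be told apart from a change of cell types.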
